A study of Mus musculus with 10 samples.

How the data were processed

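RNA was measured in liver, spleen, jejunum, ileum and distal colon of male ICR mice aged 4 or 28 months. Per the labels, RNA was extracted from each mouse and equal amounts of 6 mice at 4 months or of 9 mice at 28 months were pooled for each tissue, then labelled with a 3' in vitro transcription kit and read on 1 array per tissue and age. The mice were fed the AIN-93 diet, and the 28-month mice had been obtained at 8 months of age and the 4-month mice at 2 months. Each of the 10 groups therefore held 1 array, and the labels give no replicate, batch, position along the intestine or value per animal. The 3 intestinal arrays of 28 months are numbered and titled apart from the other 7, and whether they were prepared apart, which would coincide with age in the intestine, is not given in the sources used here.

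The values as deposited by the authors were log2 signals, 1 per probe set, already normalised between arrays by a method that is not given in the sources used here. The authors' notes name MAS5 and the affy package without version or role. The base of 2 was taken from the range of the values, from 2.71 upwards, and the array medians lay close together. Detection calls were not used here. The unit of the signals is arbitrary, so precision is limited by the number of arrays and by signal over background.

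Values were taken out of the log, and each array was scaled so that its mean signal, after trimming 2% at each end, was 500 units, with factors from 2.42 to 2.57. Signals below the median of all signals, 111 units, were set to that floor, and 48.9% to 50.9% of probe sets lay above it per array. The log2 ratio of 28 over 4 months was then taken within each tissue. Of 45101 probe sets, 34958 named 1 gene, 932 named several and 9211 were not in the probe annotation, 51 of them controls. Each of 18194 genes was represented by its probe set with the highest mean signal, and 9012 genes had more than 1. A gene counted as measured in a tissue when its signal was above the floor at either age. Genomic positions were not used here.

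A gene counted as higher or lower in a tissue from 2-fold, and as changed alike from 1.5-fold in the same direction in each tissue considered. No test between ages within a tissue was possible with 1 array per group. For 51 gene lists of tissue markers, cell types and pathways, written before the data were examined, the median log2 ratio of the measured members was placed among 10000 random lists of equal size matched in 20 bins of signal. A list of at least 5 measured members was said to stand apart at or below percentile 1 or at or above percentile 99, and lists share members. Older gene symbols in the lists were matched through synonyms unless they are current symbols of another gene. Genes were named by a rule fixed before the data were examined. It took the 12 largest ratios per tissue and direction among genes whose brighter signal reached 2 floors and whose measured probe sets all moved 1.5-fold that way. It also took up to 4 members per list with the largest ratios, the 12 genes per direction changed alike, and marker and control genes for the label check. Pearson and Spearman correlations of log2 ratios were computed between tissues. A linear model with tissue as a block and age as the term was fitted with limma, with Benjamini-Hochberg adjustment across genes, in which tissues stand in for replicates.

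Control probe sets were read to check the arrays. Probe sets at the 3' end of actin exceeded those at the 5' end by 0.59 to 2.01 on the log2 scale, and those of Gapdh by -0.00 to 1.01. The dap controls differed by 1.99 to 4.75, most in distal colon at 4 months, and hybridisation spikes averaged 11.4 to 12.6. Correlations between the 2 ages of a tissue were r = 0.987 or higher. The ileum at 4 months had r = 0.986 with the jejunum at 4 months and r = 0.987 with the ileum at 28 months.

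Alternatives fixed before the data were examined were floors at percentile 25 and percentile 75, no floor with 16 units added, scaling to equal medians, quantile normalisation, lowess within each tissue (span 0.3), the median over a gene's probe sets, removal of probe sets that can read several transcripts, fold thresholds of 1.5 and 3, limma, and leaving out each tissue. Removing genes that differed 2-fold or more between intestinal segments, and removing the pancreatic acinar list, were added after the data had been seen. The rules were tested on simulated data built from these arrays. The 2-fold rule found 99.5% of 200 genes raised by 1.5 on the log2 scale and 99.0% of 200 lowered ones, with 1 and 0 false calls, and the 1.5-fold rule in 5 tissues found 79.5% of 200 genes raised by 1. These runs held no variation between mice, and the 2-fold rule was run on liver. The shares found and the false calls hold for the simulated data only. They do not show how many genes called in the real arrays are false, such as those with 1 age at the floor.

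Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Probe sets naming several genes and probe sets without a gene name were left out of the comparisons, the former because their signal cannot be assigned to 1 gene.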

Results

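RNA from 5 tissues of male ICR mice, an outbred stock, was compared between 4 and 28 months of age. The tissues were liver, spleen and 3 segments of the intestine, namely jejunum, ileum and distal colon. RNA of 6 mice at 4 months and of 9 mice at 28 months was pooled for each tissue, and each pool was read on 1 Affymetrix mouse expression array, which measures a transcript by a set of short probes near its 3' end. The 10 arrays held 45101 probe sets each, and 34958 of these named a single gene, covering 18194 genes. Every ratio below is the signal at 28 months over that at 4 months, on the log2 scale or as a fold. Low signals were raised to a floor of 111 units, and where 1 age lay at the floor the ratio is given as a bound. With 1 array per tissue and age no difference had a replicate check and no p-value was computed within a tissue, so the number of arrays limits the precision. The remaining internal error, the median SD of log2 ratios between probe sets of the same gene, was 0.11 in jejunum, 0.14 in ileum, 0.14 in distal colon, 0.12 in liver and 0.14 in spleen.

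Marker genes were first read on all arrays to check the labels. Alb, serum albumin, gave 51037 and 50608 signal units in liver at 4 and 28 months and at most 175 elsewhere. Ms4a1, a B cell surface protein, gave 14092 and 12818 units in spleen. Hoxb13, which marks the hind end of the body axis, gave 6355 and 8492 units in distal colon and at most 47 elsewhere. Fabp6, the bile acid binding protein of the ileum, gave 20178 and 35831 units in ileum and at most 429 elsewhere. Eif2s3y, from the Y chromosome, gave 1350 to 2135 units on the 10 arrays, and Xist, the RNA of the inactive X chromosome, stayed at 144 units or less. The ileum array of 4 months carried genes of the upper small intestine beside Fabp6, with Lct, lactase, at 14054 units against 92 at 28 months. The jejunum arrays carried pancreatic enzyme genes at both ages, with Cela2a at 10404 and 9811 units.

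**Figure D1:**
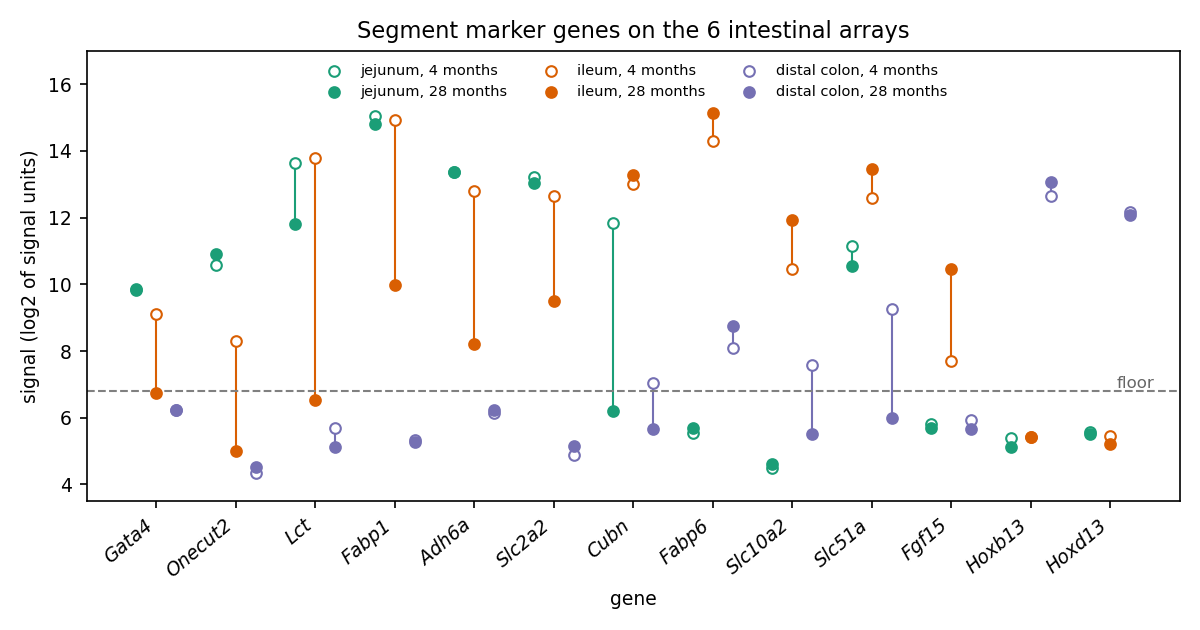
Signals (log2 of signal units, vertical axis) of 13 marker genes of intestinal segments (horizontal axis) on the 6 intestinal arrays, open circles for 4 months and filled circles for 28 months, 1 array each, with the floor at 6.79 as a dashed line. Lct, Fabp1, Adh6a, Slc2a2, Gata4 and Onecut2 lay lower in the ileum at 28 months than at 4 months, Fgf15 and Slc10a2 lay higher there, and Cubn was lower in the jejunum.

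The first comparison asked how gene expression differed between young and aged mice in the jejunum. Lists of absorptive enterocyte genes and ileum markers had medians below 0 at 28 months, while lists of genes of dividing cells, plasma cells and macrophages had medians above 0. Cubn, a receptor for vitamin B12 bound to intrinsic factor, was at least 32.8-fold lower, Slc5a12, a sodium-coupled lactate transporter, at least 22.8-fold, and Nts, which encodes the gut hormone neurotensin, at least 18.8-fold. Defa31, an alpha-defensin of Paneth cells, dropped from 14837 to 356 units, 41.7-fold. Ceacam10 was at least 7.61-fold higher, and Reg2, a regenerating-family protein, was 2.92-fold higher.

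Of 12337 genes measured in the jejunum, 29 were 2-fold or more higher at 28 months and 122 were 2-fold or more lower. Without genes graded along the intestine the numbers were 17 and 20, and at 1.5-fold 239 and 369. Among the genes that fell were also Rps4l (at least 11.2-fold), Pmp22 (10.5-fold), Dnase1 (9.51-fold), Slc5a4b (8.36-fold), Bcl2l15 (8.26-fold), Naaladl1 (8.24-fold), the antimicrobial lectin gene Reg3a (8.06-fold) and Clca4a (7.80-fold). The genes that rose most after Ceacam10 included several of plasma cells and immunoglobulins. The kappa light chain segments Igkv4-68, Igkv6-20, Igkv6-14 and Igkv4-72 were 3.46-, 3.46-, 2.62- and 2.41-fold higher. Pou2af1, a B cell transcriptional coactivator, rose 2.54-fold, Mzb1, a chaperone for antibody assembly, 2.33-fold, and Tnfrsf13b, a receptor for B cell survival factors, 2.33-fold. Mid1 rose 2.96-fold, Clca3b at least 2.78-fold and Slpi, a leukocyte protease inhibitor, 2.45-fold.

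In the absorptive enterocyte list 20 of 21 measured jejunal genes had ratios below 0 and 5 fell 2-fold or more, with a median of -0.63 at percentile 0.00 of random lists. Its members with the largest ratios were Lct at -1.81 and the brush border peptidases Anpep at -1.53, Dpp4 at -1.17 and Mep1a at -1.13. All 5 measured ileum markers were below 0 (median -0.75, percentile 0.03), including Ceacam20 at -1.51 and the bile acid exporter subunits Slc51b at -0.75 and Slc51a at -0.60. Interferon response genes had a median of -0.22 (percentile 0.00) with 0 of 21 past 2-fold, and Oasl2 and Ifit1 both stood at -0.74. All 24 cell proliferation genes were above 0, with 0 past 2-fold and a median of 0.48 (percentile 100.0), led by Aurkb at 0.76, Nusap1 at 0.71 and Plk1 at 0.65. Plasma cell genes had a median of 0.34 (percentile 99.99) with 3 of 15 up 2-fold, Irf4 among them at 1.23. Cholesterol synthesis genes had a median of 0.34 (percentile 100.0; Fdft1 0.67, Idi1 0.63), MHC class II genes 0.35 (percentile 99.97; H2-Eb1 0.59), macrophage genes 0.31 (percentile 99.99; Msr1 0.66, Lyz2 0.61) and intestinal stem cell genes 0.31 (percentile 99.92; Znrf3 0.71, Olfm4 0.54), none of them with a member past 2-fold. Fatty acid synthesis (0.20), tight junction (-0.21), proximal intestine marker (-0.21) and liver marker (0.40) lists stood apart too but not under every other setting tried, and the liver marker median changed sign without a floor.

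Of the 151 genes past 2-fold in the jejunum, 114 also differed 2-fold or more between intestinal segments, which was 75.5% against 16.9% of all genes measured. The differences between segments were taken from the same arrays, so a large change in 1 segment can itself make a gene count as graded, here and in the other segments. On the gradient between jejunum and distal colon, 69 of the 151 moved toward the colon level and 23 toward the jejunum level. No sampling position is given for the jejunum pieces in the sources used here. A part of position in the falls of ileum markers and Cubn was not tested. Of 14 pancreatic acinar genes 7 were above 0 and 7 below in the jejunum, with 0 past 2-fold. Immunoglobulin and defensin probe sets can read several family members, so the value of a single segment gene is uncertain.

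The second comparison concerned the ileum, which had the largest number of genes past 2-fold among the 5 tissues. Several genes that the upper small intestine uses for digestion and fat handling were far lower at 28 months, and 2 genes of ileal bile acid handling were higher. Lct, the enzyme that splits milk sugar, dropped from 14054 units to below the floor, at least 127-fold. Fabp1, a fatty acid binding protein, was 30.5-fold lower, Apoc2, a cofactor of lipoprotein lipase, 25.3-fold, and Gip, a hormone of the upper gut, 28.8-fold. Fgf15, the hormone through which the ileum restrains bile acid synthesis in liver, was 6.77-fold higher, and Slc10a2, the apical bile acid transporter, was 2.75-fold higher.

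Of 12513 genes measured in the ileum, 106 were 2-fold or more higher at 28 months and 208 were 2-fold or more lower, a balance that turned at 1.5-fold, with 647 higher and 518 lower. The genes with the largest falls also included Dnase1 (77.2-fold), the glucuronosyltransferase gene Ugt2a3 (at least 30.3-fold), Adh6a (23.6-fold), Hsd17b6 (at least 20.1-fold), Reg1 (14.9-fold), Slc5a12 (-3.88), Enpp3 (14.6-fold) and Cyp3a11, a drug-metabolising cytochrome P450 (13.8-fold). Ceacam10 rose 3.82-fold, Hsd11b2, which inactivates glucocorticoids, 3.28-fold, Tfcp2l1 3.14-fold, Best2, a chloride channel, 3.09-fold, Mid1 3.07-fold, Rnf180 2.71-fold and Plscr2 at least 2.88-fold. The homeobox genes Hoxc8 and Hoxb6, which encode position along the body axis, rose 2.97- and 2.84-fold, and Insl5, a hormone of colonic endocrine cells, rose 2.83-fold.

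All 10 measured proximal small intestine markers were below 0 in the ileum and 7 fell 2-fold or more (median -2.73, percentile 0.00), with Cyp2b10 at -3.45. Of 21 absorptive enterocyte genes 9 fell and 1 rose 2-fold (median -0.84, percentile 0.00), with the sugar transporter Slc2a2 at -3.15 and the apolipoprotein Apoa4 at -2.55. Cytochrome P450 and phase II genes fell in 4 of 19 cases (median -0.37, percentile 0.00; Gstm3 -2.59), and gluconeogenesis and glycolysis genes in 2 of 16 (median -0.46, percentile 0.00; G6pc -1.73, Pck1 -1.26). Interferon response genes had a median of -0.31 (percentile 0.00) with 2 of 21 down 2-fold, Ifit1 at -1.06 and Cxcl9 at -1.03. All 8 ileum markers were above 0 (median 0.84, percentile 100.0). All 16 cholesterol synthesis genes were above 0 and 4 rose 2-fold (median 0.87, percentile 100.0), namely Fdft1 at 1.12, Cyp51 at 1.12, Sqle at 1.03 and the regulator Srebf2 at 1.01. Of 16 smooth muscle genes 15 were above 0 with a median of 0.71 (percentile 100.0), including Synpo2 at 1.00, Myh11 at 0.95 and Actg2 at 0.92. Goblet cell genes had a median of 0.37 (percentile 100.0; Retnlb 1.21, Atoh1 0.78) with 1 of 14 past 2-fold, and fatty acid synthesis genes a median of 0.52 (percentile 100.0) although Dgat2 and Srebf1 fell, at -1.53 and -1.43, and Scd2 rose, at 1.38. The hepatocyte list stood at -0.38 (percentile 0.31), with Ttr at 0.88 and Apoh at -0.61.

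A further 12 lists stood apart in the ileum and did not do so under every other setting tried. Bile acid metabolism genes had a median of 0.80 in the ileum, with Cyp27a1 at -1.14 and Abcc2 at -1.08 against the rise of Fgf15 and Slc10a2. Mast cell and eosinophil genes stood at -0.88, with Mcpt2 at -1.61 or lower, and cytotoxic lymphocyte genes at -0.55, with the granzymes Gzmb at -1.38 and Gzma at -1.27. Tuft cell (-0.39), distal colon marker (-0.49), pancreatic acinar (-0.36) and oxidative phosphorylation (-0.21) lists lay lower, and stem cell (0.30), clock (0.27), MHC class II (0.26), immediate early (0.23) and enteric neuron (0.23) lists lay higher. Of the 314 genes past 2-fold in the ileum, 274 differed 2-fold or more between segments, or 87.3% against 17.2% of all measured, partly because the ileum arrays helped define them, and the count without such genes was 40. Enpp3 was read by 4 probe sets whose ratios had an SD of 1.64, so its size is uncertain.

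**Figure D2:**
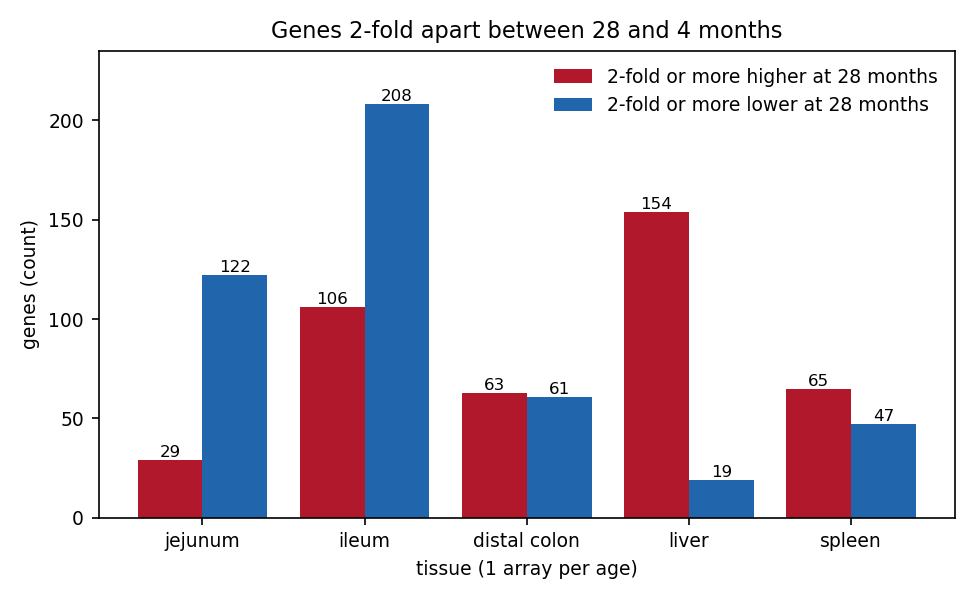
Number of genes (vertical axis, count) 2-fold or more higher (red) or lower (blue) at 28 than at 4 months in each tissue (horizontal axis), 1 array per tissue and age, with no error bar because no group had replicates. Lower genes outnumbered higher ones in jejunum (122 and 29) and ileum (208 and 106, though not at 1.5-fold, with 518 and 647), and higher genes outnumbered lower ones in liver (154 and 19).

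In the distal colon, lists of B cell, plasma cell and T cell genes had medians above 0 at 28 months, and lists of extracellular matrix, smooth muscle and host defence genes had medians below 0. Ms4a1, the B cell protein CD20, rose 2.85-fold and Cxcl13, the chemokine that draws B cells into follicles, rose 2.97-fold, from 2685 to 7984 units. Reg3b, an antimicrobial lectin, dropped from 10366 units to below the floor, at least 93.6-fold, and its relative Reg3g dropped at least 15.8-fold. The collagen gene Col1a1 had a ratio of -1.36.

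Of 12365 genes measured in the distal colon, 63 were 2-fold or more higher at 28 months and 61 were 2-fold or more lower. That balance moved with the setting, to 15 higher and 34 lower under the higher floor, 8 and 29 at 3-fold, and 31 and 14 without genes graded along the intestine. Pla2g2a, a secreted phospholipase of antimicrobial action, rose 5.21-fold, Aqp4, a water channel, 3.27-fold, Prdm14 3.66-fold, Apob, the backbone protein of chylomicrons, 3.19-fold, Ms4a4b 3.29-fold, and Ppy, pancreatic polypeptide, 2.89-fold. Igkv6-14 rose 5.27-fold, Igkv6-20 at least 3.68-fold, Igkv9-120 3.53-fold and Pou2af1 2.79-fold. Epithelial enzymes and transporters were among those that fell, including Cyp2c65 (10.3-fold), Cyp4b1 (6.29-fold), Cyp2c55 (4.84-fold), the carboxylesterase Ces1g (at least 10.3-fold), intestinal alkaline phosphatase Alpi (at least 8.78-fold), Ugt2b5 (at least 6.59-fold) and Slc51a (at least 5.55-fold). Tmigd1 fell 13.5-fold, 1810065E05Rik 12.3-fold and Sptssb at least 10.4-fold, the last from the brighter of 2 probe sets whose ratios had an SD of 1.70, so its size is uncertain.

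All 13 measured B cell genes were above 0 in the distal colon and 7 rose 2-fold (median 1.02, percentile 100.0), including Bank1 at 1.20, Fcmr at 1.18 and Cd37 at 1.14. The spleen marker list, which shares 4 genes with the B cell list, had a median of 1.02 (percentile 100.0). Plasma cell genes rose 2-fold in 5 of 15 cases (median 0.43, percentile 100.0; Ighm 1.46, Mzb1 1.29), T cell genes in 3 of 11 (median 0.43, percentile 99.98; Il7r 1.37, Cd3d 1.17) and inflammatory chemokines in 2 of 16 (median 0.32, percentile 100.0; Ccl5 1.44). MHC class I genes had a median of 0.30 (percentile 99.99; Psmb9 0.40) with 0 of 10 past 2-fold. All 16 cholesterol synthesis genes were above 0, with 0 past 2-fold and a median of 0.60 (percentile 100.0; Fdps 0.95, Idi1 0.84). All 25 extracellular matrix genes were below 0, 1 of them 2-fold, with a median of -0.63 (percentile 0.00), Fn1 at -0.87 and Col6a3 at -0.87. All 16 smooth muscle genes were below 0, with 0 past 2-fold and a median of -0.52 (percentile 0.00; Synpo2 -0.92, Myocd -0.86, Myh11 -0.82). Enteric neuron and glia genes had a median of -0.21 (percentile 0.08; Vip -0.91) and bile acid genes one of -0.27 (percentile 0.04), with 1 of 10 down 2-fold.

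Host defence genes had a median of -0.35 in the distal colon (percentile 0.01), with 3 of 11 down 2-fold and Saa3 at -2.07 or lower. Interferon response (0.27; Oasl2 at least 1.01), MHC class II (0.30; H2-Ob 0.72), ileum marker (-0.25), absorptive enterocyte (-0.22) and female-biased liver gene (-0.21) lists stood apart as well, but like host defence not under every other setting. Goblet cell genes had a median of 0.28 (percentile 100.0), which turned to -0.08 without genes graded along the intestine. Those graded genes made up 79 of the 124 past 2-fold in the distal colon, and the count without them was 45. Some genes of the small intestine were above the floor in the 4-month colon and below it at 28 months, with Alpi at 972 units, Slc51a at 614 and Slc10a2 at 190, against 82, 64 and 45, but Fabp6 went from 272 to 429 and Ceacam20 from 1042 to 1069.

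The fourth comparison was made in the liver, where 89.0% of the genes past 2-fold were higher at 28 months. Lists of acute phase, macrophage, granulocyte, interferon response and cholesterol synthesis genes had medians above 0, with most members of each short of 2-fold. Lcn2, an iron-sequestering protein of the acute phase, rose from 188 to 9366 units, 49.8-fold. The acute phase genes Orm2, Saa2 and Saa1 were 18.7-, 17.5- and 6.29-fold higher, Saa2 reaching 21785 units. BC023105 was 9.17-fold lower and Mup5, a major urinary protein, 5.15-fold lower.

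Of 12033 genes measured in the liver, 154 were 2-fold or more higher at 28 months and 19 were 2-fold or more lower. Moxd1 rose 15.1-fold, Nnmt, nicotinamide N-methyltransferase, 9.27-fold, and Tff3, a trefoil peptide of mucous epithelia, 7.64-fold. Jchain, which joins polymeric antibodies, rose at least 13.9-fold, Igha 10.5-fold, Igkv8-30 at least 10.5-fold, and Cxcl13 at least 7.92-fold. Prtn3, a protease of granulocyte precursors, rose at least 10.2-fold. Genes that fell also included Rps4l (3.96-fold), the heat shock gene Hspa1a (3.52-fold), the zinc transporter Slc39a4 (3.06-fold), Obp2a (2.82-fold), 9630013D21Rik (2.80-fold), Slc25a30 (2.62-fold), the liver transcription factor Onecut1 (2.57-fold), Cyp4a31 (2.54-fold), E2f8, which acts in hepatocyte polyploidisation (2.50-fold), and Cyp4a14 (2.36-fold).

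Of 22 acute phase genes 20 were above 0 in the liver and 7 rose 2-fold (median 0.58, percentile 100.0). Of 20 macrophage genes 5 rose 2-fold and 16 lay 1.5-fold or more higher (median 0.90, percentile 100.0), including the scavenger receptor Marco at 1.83, C1qb at 1.58, Lyz2 at 1.56 and Cd68 at 1.14. Neutrophil and granulopoiesis genes rose 2-fold in 5 of 12 cases (median 0.76, percentile 100.0), with S100a8 at 2.63 and S100a9 at 2.06, and interferon response genes in 6 of 22 (median 0.58, percentile 100.0), with Usp18 at 2.59, Ifit1 at 2.29, Oasl1 at 1.66 and Irf7 at 1.49. Cholesterol synthesis genes rose in 6 of 16 cases (median 0.89, percentile 100.0), led by Sqle at 2.23 and Msmo1 at 1.63. The senescence list had a median of 0.55 (percentile 100.0) with 1 of 10 past 2-fold, Cxcl13, and the cell cycle inhibitor Cdkn1a stood at 0.97. Cell proliferation genes rose in 2 of 13 cases (median 0.33, percentile 100.0), the replication helicase genes Mcm3 at 1.08 and Mcm6 at 1.04. Fetal liver and tumour markers rose in 5 of 10 cases (median 0.77, percentile 100.0), among them Ly6d at 1.71 and Afp, alpha-fetoprotein, at 1.23 or higher. Immediate early genes rose in 2 of 15 (median 0.57, percentile 100.0; Egr1 1.23, Ier3 1.02). MHC class I genes (median 0.45, percentile 100.0; Tapbp 0.74) and the adipocyte list (median 0.36, percentile 99.98; Pparg 0.74) had 0 members past 2-fold, and complement genes, of which 3 are shared with the macrophage list, had a median of 0.18 (percentile 99.99). Of 28 oxidative phosphorylation genes 26 were below 0 with 0 past 2-fold (median -0.16, percentile 0.02; Ndufb3 -0.32).

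Further lists that stood apart in the liver did not do so under every other setting. They were antioxidant genes (0.22; Mt2 1.98, Mt1 1.63, Hmox1 1.10), clock genes (0.20; Per1 0.60), chemokines (0.15; Cxcl14 at least 2.68), host defence genes (0.40), male-biased genes (-0.14; Ugt2b38 -1.19, Elovl3 -0.73), heat shock genes (-0.13; Hspa1b -0.81) and pancreatic acinar genes (-0.23; Prss2 -0.44). The plasma cell median of 0.16 turned to -0.03 under a higher floor, and the fatty acid synthesis median of 0.15 turned to -0.05 with the median of probe sets. Hepatocyte genes had a median of -0.01 and a mean of 0.06 over 13 genes and did not stand apart. Under the higher floor the number of liver genes past 2-fold was 62, and 25 of the 173 rested on a bound because 1 age lay at the floor. The excess of 3' over 5' actin signal was 1.70 at 4 and 2.01 at 28 months in liver, the latter the highest of all arrays. That of Gapdh was 0.53 and 0.98. A part of this difference in the ratios was not tested.

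In the spleen, lists of granulocyte, cell division, red cell and platelet genes had medians above 0 at 28 months, and the B cell list had a median below 0. Ccl8, a monocyte chemokine, rose 10.2-fold and Gzmk, a granzyme of effector T cells, rose at least 9.11-fold. The cytotoxic lymphocyte list, which holds Gzmk, did not stand apart, with a median of -0.02 and 3 of 16 genes up and 2 down 2-fold. Nor did the T cell list, with a median of -0.03. The granule genes Prtn3, Mpo and Ctsg rose 4.52-fold, 4.33-fold and at least 4.34-fold. The 12 named genes with the largest falls were led by digestive enzymes of the exocrine pancreas, such as the elastase gene Cela2a, which dropped from 8306 units to below the floor, a ratio of -6.23 or lower.

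Of 11941 genes measured in the spleen, 65 were 2-fold or more higher at 28 months and 47 were 2-fold or more lower, and at 3-fold 20 were higher and 26 lower. Slpi rose 5.99-fold, Wfdc21 5.36-fold, the granzyme gene Gzmm 4.31-fold, LOC664787 3.74-fold, Slfn4 3.67-fold, Apol11b 3.64-fold and Lcn2 3.45-fold. Among the genes that fell were trypsinogen Prss2 (43.9-fold), Ctrl (40.7-fold), Cpb1 (at least 37.9-fold), Ctrb1 (at least 37.0-fold), Cpa1 (-4.91 or lower), Rnase1 (at least 28.8-fold), Clps, pancreatic colipase (at least 27.4-fold), Zg16 (25.6-fold), Pnliprp1 (at least 24.1-fold) and Cel (at least 19.5-fold). All 14 measured pancreatic acinar genes fell 4-fold or more (median -4.81, percentile 0.00), and without that list 33 genes remained in the count of lower genes. Those 33 still held 7 exocrine pancreas genes from outside the list, such as Sycn at -4.09 or lower. They also held 2210010C04Rik, at least 56.2-fold lower. Its 3 probe sets had ratios with an SD of 3.16, so its size is uncertain.

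All 15 measured neutrophil and granulopoiesis genes were above 0 in the spleen and 11 rose 2-fold (median 1.39, percentile 100.0). All 24 cell proliferation genes were above 0, with 0 past 2-fold and a median of 0.61 (percentile 100.0; Plk1 0.91, Tpx2 0.90, Bub1b 0.85). All 13 erythroid genes were above 0 (median 0.54, percentile 100.0; Rhag 0.81, Gata1 0.74, Slc4a1 0.65), as were all 11 megakaryocyte and platelet genes (median 0.46, percentile 100.0; Tubb1 0.69), with 0 past 2-fold in both lists. Of 22 interferon response genes 21 were above 0 and 1, Oas1a at 1.10, rose 2-fold (median 0.46, percentile 100.0). Chemokines rose in 4 of 15 cases (median 0.35, percentile 100.0; Ccl4 1.52, Ccl5 1.20). Plasma cell genes had a median of 0.37 (percentile 100.0; Creld2 0.88, Igha 0.80) with 0 of 15 past 2-fold. Ighm stood at 0.16 by its brightest probe set, but other probe sets of Ighm reached up to 3.04. All 14 B cell genes were below 0, with 0 past 2-fold and a median of -0.42 (percentile 0.00), including the follicular markers Fcer2a at -0.79 and Cr2 at -0.66. Antioxidant genes had a median of 0.26 (percentile 99.98; Mt2 1.15), glycolysis genes 0.25 (percentile 99.54; Pfkm 0.58), and mast cell and eosinophil genes 0.39 (percentile 99.47; Cpa3 at least 1.04).

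Exhaustion and regulatory T cell genes had a median of 0.57 in the spleen, with Ctla4 at 1.34 and Tox at 1.06, acute phase genes one of 0.72, with Hp at 1.51 and Socs3 at 1.20, and host defence genes one of 1.00 over 5 genes, with Lcn2 at 1.79 and Reg1 at -2.35 or lower. Macrophage (0.18; Marco -0.70), complement (0.26; C1qb 0.63), oxidative phosphorylation (0.12), female-biased liver gene (0.37), MHC class II (-0.17) and spleen marker (-0.24; Ccr7 -0.69) lists stood apart too. None of these 9 lists did so under every other setting tried. Under the higher floor the number of spleen genes past 2-fold was 49.

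**Figure D3:**
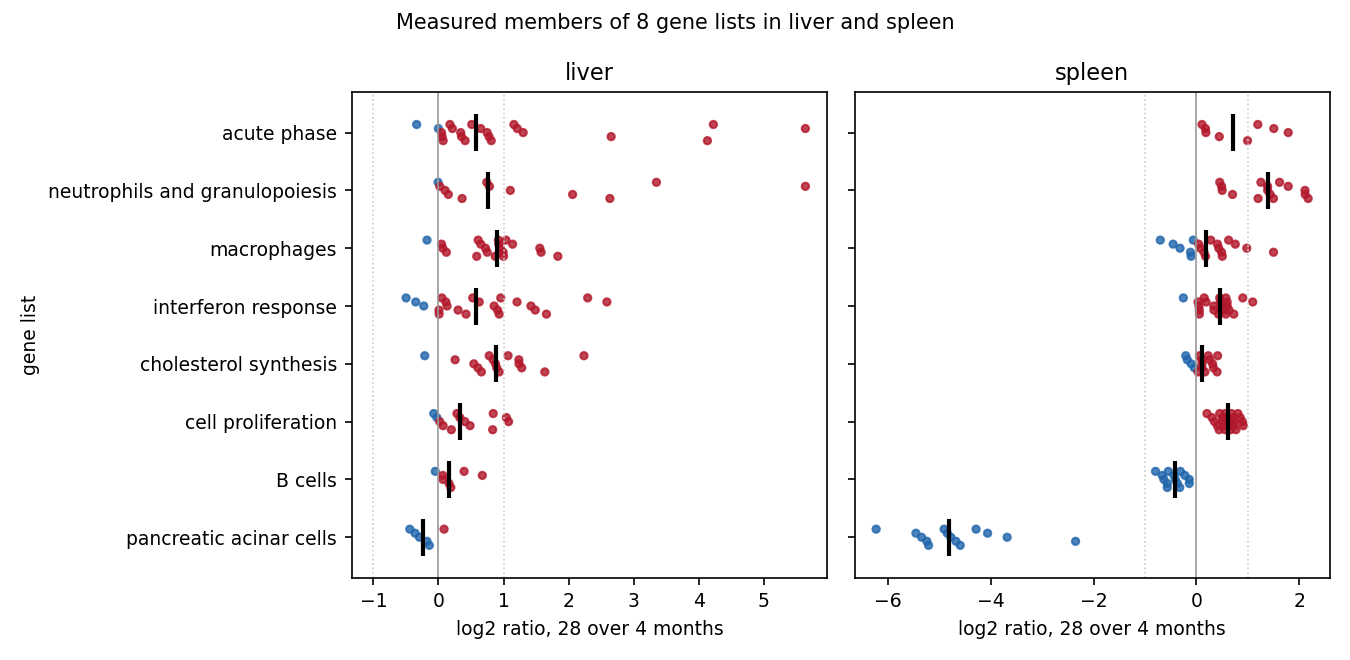
Log2 ratios of 28 over 4 months (horizontal axes) of the measured members of 8 gene lists (vertical axis) in liver and spleen, 1 point per gene, red above 0 and blue below, with the median as a black bar and 2-fold as dotted lines. Neutrophil and granulopoiesis genes had medians of 0.76 in liver and 1.39 in spleen, and pancreatic acinar genes one of -4.81 in spleen.

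Ratios were then set side by side across tissues. The tissues were taken to come from the same 2 sets of mice, although the labels number no mice. Among 10354 genes measured in all 5 tissues, each read by its brightest probe set, only Lrg1 was 1.5-fold or more higher in each. Lrg1, a plasma glycoprotein of the acute phase, did not pass after quantile normalisation or under the higher floor. Its ratios were 1.04 in jejunum, 0.64 in ileum, 0.64 in distal colon, 1.15 in liver and 1.25 in spleen. Rps4l, a ribosomal protein gene, was the only gene 1.5-fold or more lower in all 5. Its ratios were -3.48, -3.55, -1.55, -1.99 and -0.70 in the same order, all but the liver value being bounds. Single probe sets of Gtpbp4, Ighm, Xaf1 and Pnpt1 were also 1.5-fold or more higher in all 5. So were 7 probe sets without a gene name, 1 of them at 4.01 to 5.01. Across the 3 intestinal segments, with genes again read by their brightest probe set, 18 were 1.5-fold or more higher and 6 lower, of 11660 measured in all. The higher ones included the cholesterol synthesis genes Fdft1 (0.67 in jejunum, 1.12 in ileum and 0.75 in distal colon) and Idi1 (0.63, 0.90 and 0.84), the lymphocyte receptor genes Il7r (0.78, 1.14 and 1.37) and Il18r1 (0.66, 1.03 and 1.13), and Ceacam10, Igkv6-20, Gm10451, 1700097N02Rik, Serpina1b, H2-Ea, Ddit4 and Lrg1. The lower ones were Rps4l, Cyp2j6, Sptssb, Socs3, the cholesterol exporter Abca1 (-1.14, -0.99 and -0.66) and H2-T3. Socs3, a brake on cytokine signalling, stood at -0.79, -0.73 and -1.38 in the segments, against 1.21 in liver and 1.20 in spleen.

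Exchanging the ages within tissues gave at most 1 such gene in the other 15 arrangements of 5 tissues, and at most 9 in the other 3 arrangements of the segments, against the 2 and 24 observed. With tissue as a block, limma gave 0 of 13981 genes at an adjusted p of 0.05 and 963 at an unadjusted p of 0.05, with 4 residual degrees of freedom. With no effect a share of about 0.05 of the genes would pass the unadjusted limit. The unadjusted number was not counted for the exchanged ages, so the 963 shows no effect of age. Leaving out 1 tissue gave 2 to 7 genes alike, and leaving out 1 segment gave 60 to 196. All of these rest on spread between tissues, not between animals. They also do not part age from anything else the 3 intestinal arrays of 28 months have in common, which are numbered and titled apart from the other 7.

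Jejunum and ileum had the closest ratios, with Pearson r = 0.37 and Spearman rho = 0.35 across 12087 genes, which are not independent replicates. In that pair 40 genes fell 2-fold in both, where 2.07 would be shared by unrelated lists. Liver and spleen shared 15 genes that rose 2-fold in both, against 0.42 for unrelated lists, with r = 0.15. Ileum and distal colon had r = -0.09 with 8 genes moving 2-fold in opposite directions, and the remaining pairs lay between -0.08 and 0.18. Of 238 gene list medians that could be placed among random lists, 64 lay at or above the 99th percentile and 33 at or below the 1st. Members of a list vary together and lists share members, so these numbers are no test of age. Cholesterol synthesis genes stood apart in the same direction in jejunum, ileum, distal colon and liver, and in spleen had a median of 0.11 that did not. Interferon response genes stood apart in all 5 tissues, lower in jejunum and ileum and higher in distal colon, liver and spleen, a difference between tissues that was not tested.

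**Figure D4:**
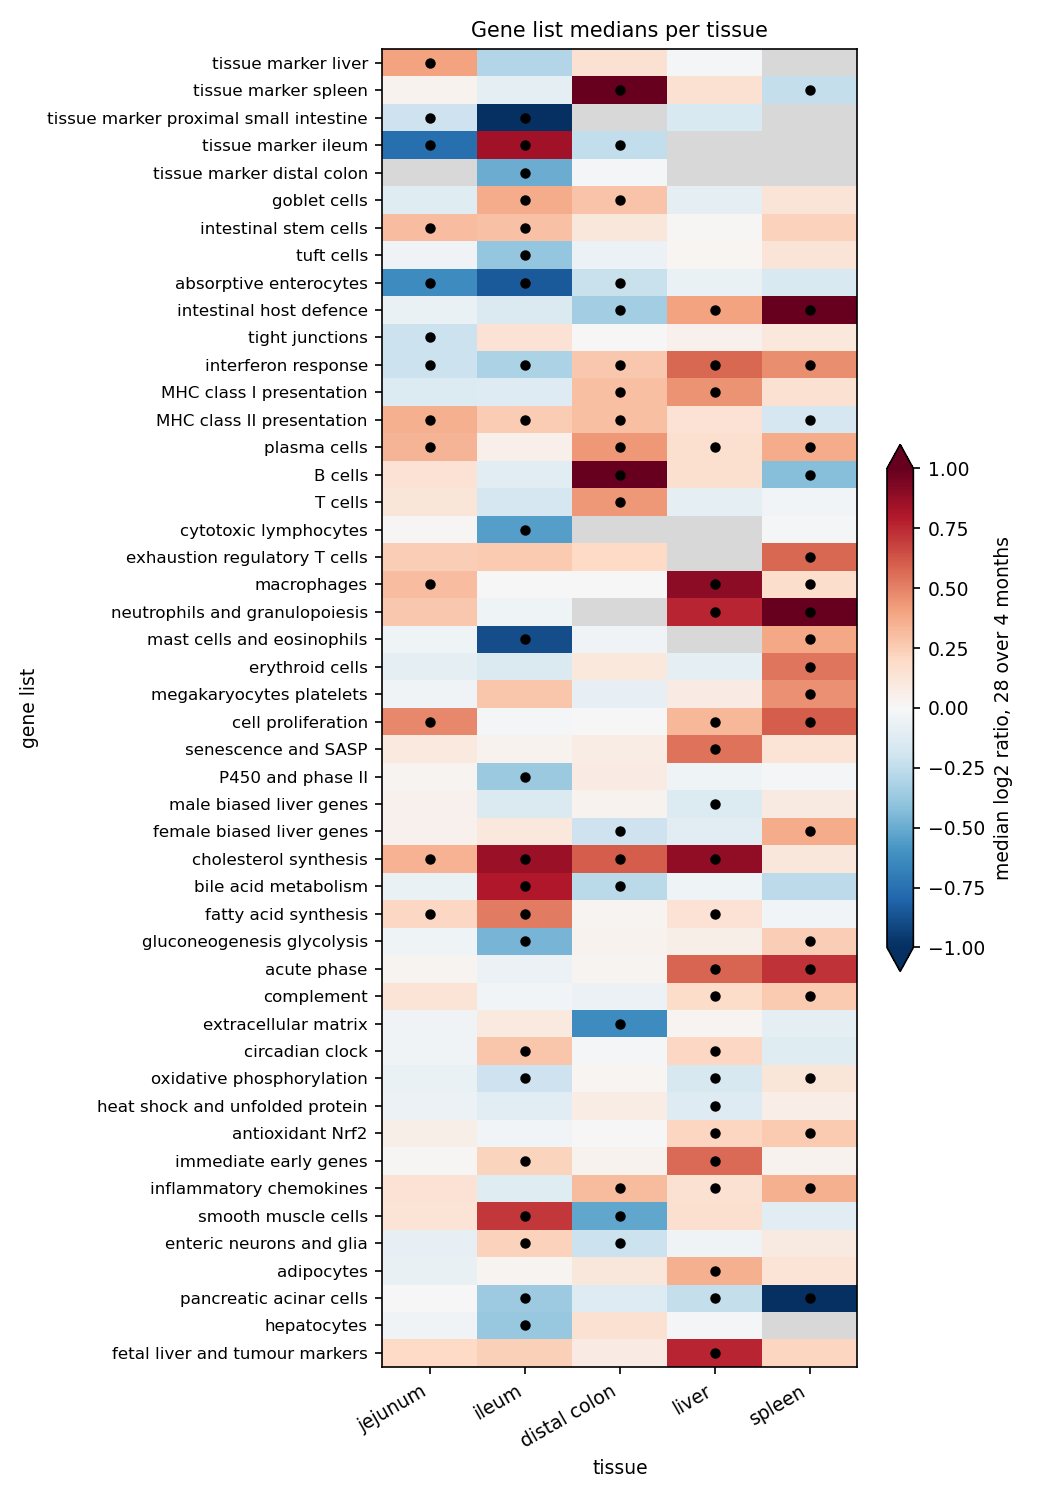
Median log2 ratio of 28 over 4 months (colour, limited to the range -1 to 1) for the gene lists (rows) that stood apart in at least 1 of the 5 tissues (columns), with a black dot where a list did so and grey where fewer than 5 members were measured. Cholesterol synthesis is red with a dot in 4 tissues, and B cells are red in distal colon (1.02) and blue in spleen (-0.42).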

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

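Of the tests in this part, those of ileum position and of the make-up of pancreatic RNA were set out before their results were seen, and the others were chosen after. No array lay apart from the other 9 on any of 6 control measures by the gap between neighbouring values.

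In the ileum at 28 months, proximal small intestinal markers had a median log2 ratio of -2.73 and ileum markers one of 0.84. Scaling between arrays was argued against, since the proximal median was -2.71 or lower under 3 other scalings, and so was distal colon RNA mixed into the pool, since 44 colon-specific genes allowed a median share of 0.925%, with 10th and 90th percentiles of -0.821 and 9.52%. A candidate explanation is that the 28-month ileum pieces came from nearer the colon than the 4-month pieces. For it, 74.8% of the 314 genes past 2-fold were graded between jejunum and distal colon and moved toward the colon. Of all genes measured in ileum 14.7% were graded in this way, in either direction. The share that moved toward the colon was 45.7% in jejunum and 37.1% in distal colon, whose own arrays defined the gradient, 11.6% in liver and 24.1% in spleen. Distal colon markers went the other way in ileum, with a median of -0.49 (percentile 0.38) and 4 of 5 below 0. That list did not stand apart under every other setting. A change of the ileum with age could also give a shift toward the colon, was not tested and stays open, as no sampling position is given in the sources used here.

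In the spleen at 28 months, all 14 pancreatic acinar genes were lower, with a median of -4.81, and 5 of them were still above the floor. Scaling between arrays was argued against, as the median stayed at -4.78 or lower under 3 other scalings. Pancreas attached to the 4-month spleen pieces may account for the difference and stays open. Of 13 measured exocrine pancreas genes outside the list, 53.8% were 2-fold or more lower. Sycn stood at -4.09 or lower and Ctrc at -3.34 or lower, while Bhlha15 stood at 0.43 and the islet gene Ins2 at -0.03. The islet genes Gcg, Iapp, Sst and Ppy lay below the floor at both ages. At 4 months Rbpjl, Pla2g1b and Ins2 gave 113, 182 and 170 units. That was too near the floor of 111 for a 2-fold fall to show, so these genes decide nothing. The signals of the acinar genes in the 4-month spleen had a Spearman rho of 0.45 with those in the 4-month jejunum, which does not decide whether the make-up was the same. All 14 were above the floor in both jejunum arrays, 2 of them stand in another list too, and a change with age in the spleen itself stays open and untested.

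Across all 5 tissues 6 probe sets with a gene name moved alike by 1.5-fold, reading Lrg1, Gtpbp4, Ighm, Xaf1, Pnpt1 and Rps4l. Sequence variants under single probe sets, at different frequencies in the 2 sets of outbred mice, could give such a pattern, and for 100% of the 3 genes other than immunoglobulins with a second measured probe set (Gtpbp4, Xaf1 and Pnpt1) another probe set stayed under 1.5-fold in at least 4 of the 5 tissues, that of Xaf1 standing at 1.05 in liver. With 3 genes the test decides nothing, 0 of 6 other probe sets of Ighm were steady, 33.3% to 57.0% of probe sets past 2-fold had a steady neighbour by a rule within 1 tissue, and an effect of age stays open. Of the 16 exchanges of ages within tissues 1, the real one, gave as many as 6 probe sets, and the highest other gave 2, in a design with too few exchanges for a share under 0.05.

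For genes changed alike in 5 tissues, 1 of 16 exchanges gave as many as the 2 found, the highest other giving 1, and for the 3 intestinal segments 1 of 4 exchanges gave as many as 24, the highest other giving 9. For limma, 16 of 16 exchanges gave as many as the real 0, the highest other also giving 0. None of these designs has enough exchanges for a share under 0.05.

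The following lists stood apart in opposite directions in different tissues, and these differences between tissues were not tested. Interferon response genes had medians of -0.22 in jejunum, -0.31 in ileum, 0.27 in distal colon, 0.58 in liver and 0.46 in spleen. B cell genes stood at 1.02 in distal colon and -0.42 in spleen, and spleen markers at 1.02 and -0.24. MHC class II genes stood at 0.35 in jejunum, 0.26 in ileum, 0.30 in distal colon and -0.17 in spleen. Ileum markers stood at -0.75 in jejunum, 0.84 in ileum and -0.25 in distal colon. Bile acid genes stood at 0.80 in ileum and -0.27 in distal colon. Smooth muscle genes stood at 0.71 in ileum and -0.52 in distal colon, and enteric neuron and glia genes at 0.23 and -0.21. Host defence genes stood at -0.35 in distal colon, 0.40 in liver and 1.00 in spleen. Oxidative phosphorylation genes stood at -0.21 in ileum, -0.16 in liver and 0.12 in spleen. Gluconeogenesis and glycolysis genes stood at -0.46 in ileum and 0.25 in spleen, and mast cell and eosinophil genes at -0.88 and 0.385. Female-biased liver genes stood at -0.21 in distal colon and 0.37 in spleen.

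Probe sets without a gene name, which the report does not use, were 2-fold or more higher at 28 months in 19 cases in jejunum, 39 in ileum, 18 in distal colon, 23 in liver and 35 in spleen, and 2-fold or more lower in 14, 13, 41, 6 and 48.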

How the results depend on the processing

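The removal of genes graded along the intestine and of the acinar list was chosen after seeing the data, and the other settings were planned. No paired analysis was possible because the labels number no mice and each group held 1 array.

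With the floor at percentile 75, the number of genes past 2-fold was 95 in jejunum, 180 in ileum, 49 in distal colon, 62 in liver and 49 in spleen, with 0 genes alike in 5 tissues and 11 alike in the segments. In distal colon 15 of these were higher, against 63 of 124 at the floor used. A higher floor leaves fewer genes measured and also shrinks ratios of low signals. The share of measured genes that passed fell in liver, from 173 of 12033 to 62 of 7068. It also fell in ileum, distal colon and spleen, but not in jejunum, with 151 of 12337 and 95 of 7435. At 1.5-fold the counts were 608, 1165, 603, 574 and 607 in the same order, and at 3-fold 38, 101, 37, 45 and 46. In ileum, where lower genes outnumbered higher ones, 647 were higher and 518 lower at 1.5-fold, and in spleen 20 were higher and 26 lower at 3-fold. Without graded genes 37 were left in jejunum, 40 in ileum and 45 in distal colon (31 higher and 14 lower), and 11 alike in the segments. Without the acinar list the spleen count was 98. The counts per tissue stayed within 1.5 times under every other floor, scaling and probe set choice.

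Genes alike in 5 tissues numbered 1 under quantile normalization, where Lrg1 no longer passed, 0 at the 2-fold threshold and 0 under limma, and leaving out 1 tissue gave 2 to 7. Genes alike in the segments numbered 1 at 2-fold, and leaving out 1 segment gave 60 to 196, since fewer tissues had to pass.

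Of the 97 list medians that stood apart, 57 did so under every planned setting that gave a value, among them acute phase, macrophage, neutrophil and cholesterol synthesis genes in liver, B cell and matrix genes in distal colon and neutrophil and B cell genes in spleen. The setting without graded genes was run in the intestinal segments only, so the liver and spleen lists among the 97 were not run. There 36 could be placed and 25 still stood apart. The median changed sign for liver markers in jejunum (-0.069 with no floor), plasma cells in liver (-0.026 with the floor at percentile 75), female-biased genes in distal colon (0.022 with no floor), fatty acid synthesis in liver (-0.049 with the median of probe sets) and goblet cells in distal colon (-0.075 without graded genes). The cause was not tested. Bile acid genes in ileum stood at 0.06 with the floor at percentile 25, and host defence genes in distal colon at -0.12 with no floor, and neither stood apart there.

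Of 987 values of named genes 0 of those past 2-fold changed sign under any setting. That outcome was nearly fixed in advance and does not test robustness. A floor or an added constant cannot flip a sign, and scaling moved the median of all genes little. Genes named for the largest ratios were also chosen with all measured probe sets moving the same way. With the floor at percentile 75, 174 values moved by more than the median spread between probe sets. So did 138 with the median of probe sets, 80 with the floor at percentile 25 and 76 with no floor. With the floor at percentile 75, 340 had no value, as had 43 without probe sets that can read several transcripts. The 11 correlation results moved by less than the SD among the pairs of tissues under the 8 settings run. That limit is wider than many of the correlations, so a weak correlation of a pair could change sign and still pass. No scaling moved the median of all genes by more than 0.1. Ratios of genes near the floor are limited by signal over background.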

Other observations

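Families read in this paragraph were chosen after their values had been seen, and their probe sets can read several family members. Immunoglobulin genes, which report antibody-making cells, had a median log2 ratio of 1.02 over 14 measured genes in distal colon, with 7 past 2-fold and 14 above 0, or 13 under 2 of 3 other scalings. In liver the median was 1.58 over 6 genes with 3 past 2-fold, in jejunum 0.52 over 15 with 6 past 2-fold, in spleen 0.21 over 14 with 1, and in ileum 0.01 over 14 with 0. Hox genes, which hold position along the body axis, had a median of 0.48 over 17 genes in ileum with 4 past 2-fold, against -0.11 over 22 in distal colon and -0.02 over 12 in jejunum. The 3 measured major urinary protein genes in liver, products that male hepatocytes secrete under growth hormone and androgen, had a median of -0.61.

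Fatty acid oxidation genes, which break down fat in mitochondria and peroxisomes, did not stand apart in any tissue, with medians of -0.04 in jejunum, -0.10 in ileum, -0.12 in distal colon, -0.12 in liver and -0.02 in spleen. Enteroendocrine genes did not either, with -0.01 in jejunum, -0.15 in ileum and -0.02 in distal colon. Paneth cell genes in jejunum had a median of -0.10 and a mean of -0.90, as Defa31 fell and Mptx1 stood at -1.93 while Mmp7 stood at 0.32. Ighm was read by 7 measured probe sets that differed, from -0.23 to 1.31 in jejunum, from -0.48 to 1.51 in ileum and from 0.16 to 3.04 in spleen.

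Among probe sets without a gene name, 7 were 1.5-fold or more higher at 28 months in all 5 tissues and 0 were lower in all 5. The largest stood at 4.27 in jejunum, 4.01 in ileum, 4.38 in distal colon, 4.31 in liver and 5.01 in spleen. The test of sequence variants covered probe sets with a gene name only.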
